A study of Arabidopsis thaliana with 6 samples.

How the data were processed

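Transcript levels were measured in roots of Arabidopsis thaliana seedlings on 6 Affymetrix ATH1 arrays, which carry probe sets for most genes known when the array was designed. Seedlings aged 5 days were moved to medium with 5 mM boric acid, a concentration in large excess of what plants need, or to the same medium without the addition, and roots were sampled after 12 h. Each condition had 3 arrays, called here boric acid 1 to 3 and control 1 to 3 by the replicate numbers in the labels. Total RNA was labelled with a kit that primes at the 3′ end of transcripts, per the labels.

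The authors processed the arrays with RMA, per the labels, which give neither a version nor parameters. The values deposited by the authors are log2 expression values per probe set, normalized across arrays. The log base was checked on the hybridization controls. The controls cre and bioB, which are added in known amounts, differed by 5.53 to 6.13 on the 6 arrays, which is near the log2 of the ratio of those amounts. Medians lay between 1.45 and 1.49 and the lowest values between -0.38 and -0.30. Which background step or baseline led to lowest values so near 0 is not stated. The TrpnX controls, which match no plant transcript, reached at most 0.217 on any array, so values of about that size are read as background.

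Of 22810 probe sets, 64 control probe sets were set aside and 22746 were tested. Probe sets were joined to genes through a table of RefSeq genes of the TAIR10.1 assembly and, where that gave none, the table of the array's probes. A single gene was found for 13513 probe sets, of which 13436 were named through RefSeq and 77 through the array's table alone. Another 503 probe sets matched several genes, and 8730 could not be named. The 13513 probe sets stand for 13355 genes. For the 147 genes with more than 1 probe set, the one with the highest mean over the 6 arrays stood for the gene. Counts below are of genes unless probe sets are named. The assembly served only for names and for which genes neighbour each other.

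Boric acid was compared with control by a linear model per probe set in limma 3.58.1 under R 4.3.3 with empirical Bayes moderation. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 22746 probe sets, and an adjusted p under 0.05 was the threshold. "Rose" and "fell" are used only for genes past it, or past 0.05 under the block or adjusted over a list alone where so stated. Changes are boric acid minus control on the log2 scale with the standard error (SE) of the fit, and group values are means with their standard deviation (SD), n = 3 arrays. Depth has no counterpart on arrays, and their number limits the precision.

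Before the data were examined, 34 gene lists were written with 646 entries, of which 635 matched a gene and 74 were also measured by a probe set of their own. Members not measured here may be among the 8730 probe sets that could not be named. At least 1 member was measured for 25 lists and at least 3 for 9 lists. Those 9 were tested with limma's camera, which compares the members with all other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 9 lists. The minimum of 3 measured members was set after the data had been examined. An estimated correlation was the alternative. The count of members past the threshold is also given adjusted over the list alone.

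The genes named were chosen by a rule fixed before the data were examined. It takes the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose boric acid arrays all lie on the same side of all control arrays. It adds every measured boron transport gene and, for each other list, up to 4 members past the threshold, or the 1 member with the largest change where none passed. It names 52 genes with the boron transport loci, 29 past the threshold and 23 not. The loci AT3G06450 and AT5G25430, known as BOR3 and BOR6, carry no such symbol in the table and were counted with them after their values were seen. COR47, COR15A, AUR1, AUR3, EXLB1, BHLH101, PYE, XTH19, XTH21, EXLA2, EXPA4, EXPA8, EXPA15, LHCB4.2, PSBY, LBD16, CR4 and all genes named only in the closing section were also chosen after their values were seen. Exceptions there are GTR1, AOP3 and AT2G31790, the measured glucosinolate genes not seen before their list was written.

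Both groups carry the replicate numbers 1 to 3 in the labels. The labels do not say what a number stands for, so arrays with the same number were checked for shared deviations from their group means. The correlations over probe sets were 0.609, 0.231 and 0.618 for the pairs numbered 1, 2 and 3, against -0.619 to 0.284 for differently numbered arrays. The pair numbered 2 lay below the highest value for differently numbered arrays. Deviations from a group mean sum to 0, so a positive correlation in a pair pushes others down. The check therefore does not establish that the numbers pair the samples. A fit with the replicate number as a block, for a possible pairing, is given beside a result where it changes the call or moves a count by more than 1.5 times. The fit without the block, fixed before the data were examined, gives all other values, and the SE of a gene's change unless the block fit is named for it.

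The comparison was tested on simulated data with 22746 probe sets, of which 200 were changed. Without the block, 39.5% of changes of 1 log2 unit and 88.5% of changes of 2 log2 units were recovered, with 5 and 14 false calls. With the block, 0% and 74.5% were recovered, with 0 and 3 false calls. The simulated noise was independent between arrays, so same-numbered arrays shared no deviations. These block values therefore do not show what the block recovers on the real arrays.

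The alternatives were the replicate block, a minimum of a 2-fold change, a moderation with intensity trend and robust settings, median centring or another quantile normalization of the arrays, leaving out the dimmest 25% or 50% of probe sets, array weights, the mean of a gene's probe sets, leaving out probe sets marked as cross-hybridizing, an adjusted p under 0.01, camera on ranks, and leaving out each array in turn. Added after the data had been examined were the fit without both arrays numbered 1, the test of lists with 1 or 2 measured members, and families of genes whose symbols share a stem. A family needed at least 8 measured members. Lists of late embryogenesis abundant, glucosinolate, seed storage and oil body, photosystem, and clock and day-rhythm genes were written from textbook knowledge after the largest changes had been seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.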

Results

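Transcript levels were compared between roots of 5-day-old Arabidopsis seedlings kept for 12 h on medium with 5 mM boric acid and roots on control medium, with 3 arrays in each group. The comparison asks which transcripts differ early in roots exposed to toxic boron. Arrays of a group correlated with each other at 0.966 to 0.992 over probe sets, and arrays of different groups at 0.958 to 0.979. The first principal component held 44.0% of the variance and separated the boric acid arrays from the control arrays. The second held 36.1%, with the highest scores on the arrays numbered 1, at 22.6 for boric acid 1 and 56.5 for control 1, against -31.0 to -8.40 for the other arrays. The difference between the 3′ and 5′ probe sets of actin, a measure of RNA quality, was also highest on these arrays, at 2.96 and 2.60 log2 units, against 1.23 to 1.71 on the others. Its mean was 1.98 ± 0.87 (SD, n = 3) in boric acid and 1.83 ± 0.70 (SD, n = 3) in control roots (two-sided exact permutation test, p = 0.7, the smallest possible being 0.1).

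**Figure D1:**
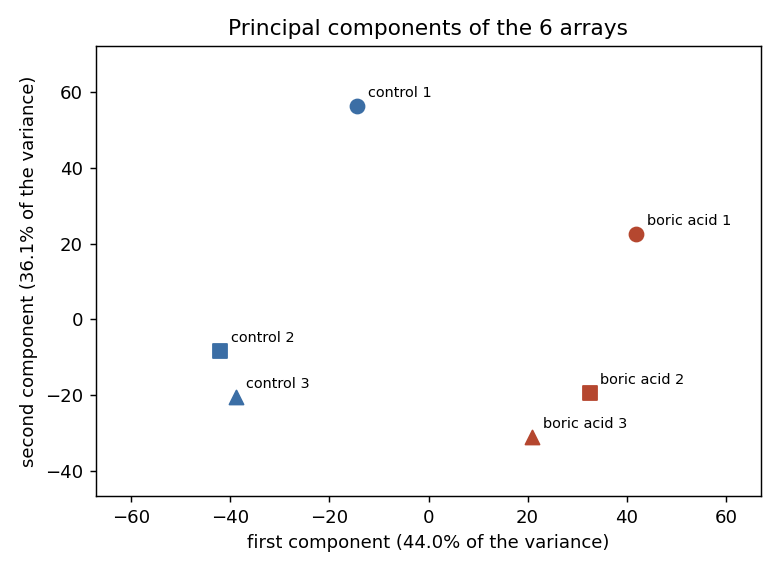
Scores of the 6 arrays on the first (44.0% of the variance) and second (36.1%) principal component of the log2 values, without units. Each point is 1 array; red, boric acid; blue, control; circles, squares and triangles, replicate numbers 1, 2 and 3. The groups separate along the first component, and both arrays numbered 1 score highest on the second.

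After 12 h in boric acid, the largest rises were those of AT3G02480 (63.9-fold), a gene of the late embryogenesis abundant family, AT2G37870 (58.4-fold), of the lipid-transfer protein superfamily, and LEA4-5 (31.4-fold), a late embryogenesis abundant gene linked to drought and abscisic acid. The largest fall was that of BCAT4, the aminotransferase that starts methionine chain elongation for glucosinolates, which fell by 5.26 ± 0.50 (SE, n = 3) on the log2 scale. Of the cell wall lists, 2 of 9 xyloglucan endotransglucosylases, 1 of 11 expansins and 2 of 6 class III peroxidases fell and none rose over all genes without the block, and no list passed as a whole (limma's camera, adjusted p = 0.300, 0.768 and 0.718). The 3 measured Aurora kinase genes of mitosis had changes between -0.83 and -0.75, none past the threshold over all genes and all 3 at an unadjusted p under 0.05. As a list they were lower in boric acid by limma's camera test (adjusted p = 0.00265), and not with an estimated correlation of 0.085 (adjusted p = 0.147). The abscisic acid response list, with an estimate of -0.18, lost its call too, so such a loss need not come from correlated members.

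In all, 362 of 13355 genes (2.71%) passed the threshold of limma's test at a Benjamini-Hochberg adjusted p of 0.05, with 216 higher and 146 lower in boric acid. With the replicate number as a block, 1047 genes passed, 619 higher and 428 lower, including all 362. Of the 8730 probe sets without a gene name, 360 passed, 210 higher and 150 lower (994 with the block). Of those matching several genes, 18 passed, 10 higher and 8 lower (38 with the block). The count of genes depended on single arrays: it was 167, 36 and 87 without boric acid 1, 2 and 3, and 573, 64 and 128 without control 1, 2 and 3.

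The largest rise was that of AT3G02480, from 1.16 ± 0.13 (SD, n = 3) in control to 7.16 ± 0.58 in boric acid, a log2 change of 5.997 ± 0.284 (SE, limma, adjusted p = 0.00209). LEA4-5 was at 0.68 ± 0.20 in control and 5.65 ± 1.00 in boric acid, a change of 4.97 ± 0.47 (adjusted p = 0.00789). AT2G37870 rose 58.4-fold (log2 change 5.87 ± 0.36, adjusted p = 0.00297). AT4G33550, also of the lipid-transfer protein superfamily, rose 29.4-fold (4.88 ± 0.48, adjusted p = 0.00868). AT5G13900, of the same superfamily, rose 9.52-fold (3.25 ± 0.60, adjusted p = 0.0456), and without 1 array it kept its call only in the fit without control 1, at changes of 2.78 to 3.78 over the 6 fits. The GDSL lipase gene AT3G50400 had a log2 change of 3.43 ± 0.58 and the cytochrome P450 gene AT5G08250 one of 2.90 ± 0.39. AT4G32950, of the protein phosphatase 2C family, rose by 3.08 ± 0.41 and the cysteine proteinase gene CP1 by 2.90 ± 0.33. AT2G21640, a nuclear gene for a mitochondrial protein and induced by oxidative stress, rose by 2.87 ± 0.22, from 1.23 ± 0.39 (SD) to 4.11 ± 0.21. AT5G07330 rose 15.9-fold and AT3G51750 by 3.08 ± 0.55. The adjusted p of these 7 genes lay between 0.00431 for AT2G21640 and 0.0421 for AT3G51750.

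BCAT4 was at 5.55 ± 1.06 (SD, n = 3) in control and at 0.29 ± 0.21 in boric acid, the latter near background (adjusted p = 0.00801). MSRB5, a methionine sulfoxide reductase, fell by 2.90 ± 0.16 (SE, adjusted p = 0.00241), from 7.77 ± 0.19 to 4.87 ± 0.21. AT4G15390, of an acyltransferase family, fell by 2.99 ± 0.21, and tny, an AP2/ERF transcription factor, by 2.61 ± 0.19 (adjusted p = 0.00387 for both). AT4G21870, related to small heat shock proteins, fell by 2.75 ± 0.29, and AT4G07820, of the family of pathogenesis-related protein 1, by 2.65 ± 0.34. AT3G18450, of the PLAC8 family, fell by 2.48 ± 0.13 and the chitinase family gene AT1G56680 by 2.41 ± 0.24, both to a level under 1 in boric acid (0.35 ± 0.18 and 0.79 ± 0.42, SD). The changes of AT1G78020, AT4G29690 and AT1G21440 were -2.69 ± 0.33, -2.31 ± 0.14 and -2.28 ± 0.16. XTH16 had the smallest of the 12 falls, by 2.26 ± 0.27, from 3.44 ± 0.51 (SD) to 1.18 ± 0.25 (adjusted p = 0.0135).

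**Figure D2:**
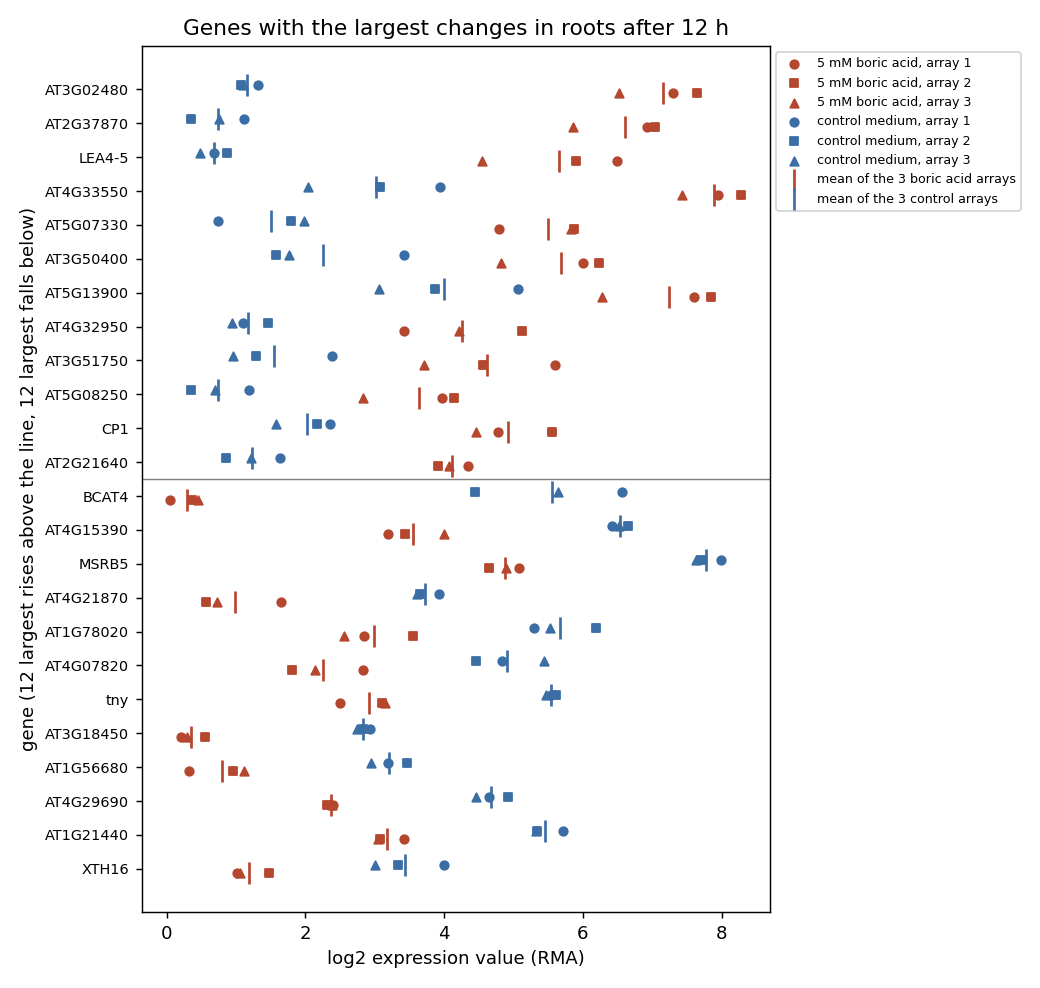
Log2 expression values of the 12 genes with the largest rises and the 12 with the largest falls on each of the 6 arrays. Red, boric acid; blue, control; circles, squares and triangles, arrays numbered 1, 2 and 3; vertical bars, means of 3 arrays. For each gene the boric acid arrays lie on the same side of all control arrays, with changes from 2.87 to 5.997 for the rises and from -5.26 to -2.26 for the falls.

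Not all of these calls held without single arrays. Of the 29 named genes past the threshold, 7, 17 and 11 lost the call without boric acid 1, 2 and 3, and 2, 16 and 7 without control 1, 2 and 3, with no change of sign. In all 6 such fits 10 kept it: AT3G02480, AT2G37870, AT2G21640, AT4G15390, MSRB5, tny, AT3G18450, AT4G29690, AT1G21440 and AT5G64120. LEA4-5, BCAT4 and AT1G56680 lost it only without boric acid 2. Over the 6 fits the change of LEA4-5 ranged from 4.55 to 5.52 and that of BCAT4 from -5.81 to -4.75.

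Of 34 genes written for the abscisic acid response, 4 were measured by a named probe set, and others may be among the probe sets without a gene name. Among these 4, LEA4-5 and the dehydrin LTI30 rose and 2 did not pass. LTI30 went from 8.13 ± 0.15 (SD, n = 3) to 9.20 ± 0.12, a change of 1.06 ± 0.12 (SE, adjusted p = 0.0121). LTI30 lost the call without boric acid 2, boric acid 3 or control 2, at changes between 1.02 and 1.15 over the 6 fits without 1 array. Adjusted over the list alone 3 rose, the third being the dehydrin COR47 with a change of 0.65 ± 0.17. The cold-regulated gene COR15A, at 0.20 in boric acid and 0.17 in control, was near background. As a list they were higher against the other genes by limma's camera test (adjusted p = 0.000508), and with an estimated correlation that call was lost (adjusted p = 0.135). The estimate was -0.18, under the preset of 0.01, so the loss does not come from members that vary together. All 4 are also members of the late embryogenesis abundant list written later. They therefore cannot tell an abscisic acid response from rises within that family, and the 2 lists are not separate evidence.

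The list of genes of the G2 and M phases of the cell cycle had 3 measured members, the Aurora kinase genes AUR1, AUR2 and AUR3. Their changes were -0.79 ± 0.16, -0.83 ± 0.22 and -0.75 ± 0.20 (SE), with adjusted p = 0.0586 for AUR1 and 0.116 for the others. None passed over all genes, and 3 of 3 fell adjusted over the list alone, as they did at an unadjusted p of 0.05. With the replicate block AUR1 (adjusted p = 0.0346) and AUR3 (adjusted p = 0.0191) fell. SIM, an inhibitor of cyclin-dependent kinases, had a change of -0.91 ± 0.34 (adjusted p = 0.252, and 0.0161 with the block). PRL, a subunit of the helicase that licenses replication, was at 1.94 in boric acid and 1.99 in control.

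Of 9 measured xyloglucan endotransglucosylases, enzymes that cut and rejoin xyloglucan in the cell wall, XTH16 and XTH20 fell and 7 did not pass. XTH20 fell by 0.92 ± 0.16 (SE, adjusted p = 0.0359), a call kept only without control 3 among the fits without 1 array, at changes of -1.09 to -0.83. The count was the same adjusted over the list alone, where with the replicate block XTH21 (change -0.84 ± 0.33 without the block) fell and XTH19 (0.46 ± 0.19 without the block) rose as well. The list as a whole was not past the threshold (median change -0.19, camera adjusted p = 0.300). Of 11 measured expansins, which loosen cell walls, EXPB1 fell by 1.24 ± 0.18 (adjusted p = 0.0208) and 10 did not pass. EXPB1 kept the call only without boric acid 1 or control 1, at -1.35 to -1.09. Adjusted over the list alone, EXLB1 rose (change 0.98 ± 0.25) and EXPB1 fell, and with the block EXLB1 (adjusted p = 0.0436) and EXPA18 (adjusted p = 0.0353) rose. Adjusted over the list alone with the block, 4 rose and 3 fell, the additions being EXPA18, EXLA2 and EXPA4, which rose, and EXPA8 and EXPA15, which fell. The expansin list gave a median of 0.06 and a camera adjusted p of 0.768.

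Class III peroxidases, secreted enzymes of wall cross-linking and peroxide turnover, had 6 measured members among the 14 genes found by a pattern on gene names. Family members whose names do not match the pattern were not counted. AT5G64120 fell by 2.22 ± 0.16 (SE), from 8.79 ± 0.13 (SD, n = 3) to 6.57 ± 0.27 (adjusted p = 0.00396). Prx37 fell by 1.29 ± 0.23 (adjusted p = 0.0411), and its call was lost in each of the 6 fits without 1 array, at -1.49 to -1.11. The other 4 did not pass, and the count was the same adjusted over the list alone. The list's median was 0.11, while its mean was -0.35 and camera gave the direction down (adjusted p = 0.718). HCT, an enzyme of lignin precursor synthesis, had a change of 0.78 ± 0.20 (adjusted p = 0.105, and 0.0306 with the block).

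The 3 measured genes of the iron deficiency response had changes of -0.99 ± 0.38 for AT3G13610, the hydroxylase of coumarin synthesis, -0.66 ± 0.28 for BHLH101 and -0.45 ± 0.44 for PYE (SE). None passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 in limma. With the replicate block none passed over all genes, and all 3 fell adjusted over the list alone. As a list they gave a camera adjusted p of 0.133, and with the replicate block they were lower (adjusted p = 0.0343). With an estimated correlation and no block the list was not past the threshold (adjusted p = 0.336). Boron transport was represented only by AT3G06450, with a change of 0.22 ± 0.15 (adjusted p = 0.564), and AT5G25430, which was near background in both groups at 0.30 and 0.28. The other genes of that list, BOR1 and BOR4 among them, had no named probe set, so their response is not known.

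None of 9 measured auxin genes passed over all genes or adjusted over the list alone, and 1, LBD16 (change -0.46 ± 0.12, SE), had an unadjusted p under 0.05 in limma. The largest change was 0.51 ± 0.32 (SE) for WES1, which conjugates auxin to amino acids. The list's median was -0.16, its mean 0.00, and camera's direction down (adjusted p = 0.768). Of 3 jasmonate genes, none passed over all genes, and OPCL1, an enzyme of jasmonate synthesis, had a change of -0.68 ± 0.16 and fell adjusted over the list alone, as at an unadjusted p under 0.05. The jasmonate list had a median of 0.05, a mean of -0.17 and the direction down (camera adjusted p = 0.730). None of 4 genes of the root meristem and cap passed over all genes or adjusted over the list alone, and 1, CR4 (change 0.33 ± 0.13), did at an unadjusted p under 0.05 (camera adjusted p = 0.317). UPB1, a regulator of peroxide balance at the root tip, had a change of 0.72 ± 0.38.

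**Figure D3:**
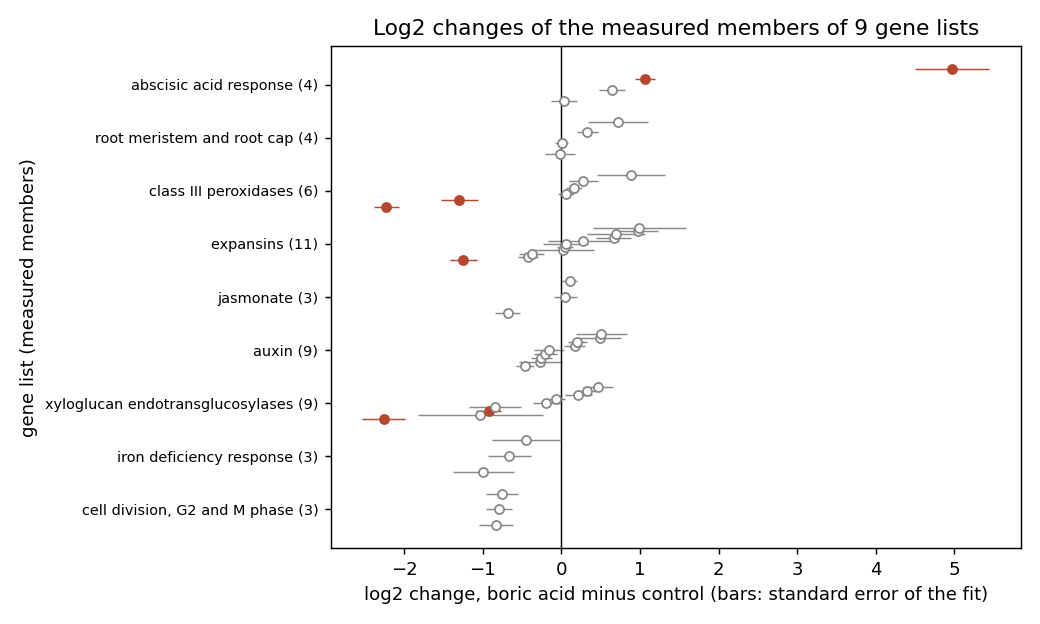
Log2 change, boric acid minus control, of each measured member of the 9 gene lists with at least 3 measured members. Points are genes, bars the SE of the fit (n = 3 arrays per group), filled points genes past an adjusted p of 0.05 over all probe sets; the number of measured members follows each list's name. The 4 abscisic acid response genes lie at or right of 0 and the 3 genes of the G2 and M phases left of it.

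A further 16 lists had only 1 or 2 measured members, none past the threshold over all genes in limma and 6 at an unadjusted p under 0.05. With the replicate block, SIM, HCT, EXPA18, NDB2 and WRKY6 passed. NDB2, an alternative NADH dehydrogenase of mitochondria, had a change of 1.51 ± 0.46 (SE, adjusted p = 0.159, and 0.0281 with the block). WRKY6, a transcription factor of defence and senescence, had one of 0.78 ± 0.26 (adjusted p = 0.190, and 0.0381 with the block), and EXPA18, expressed in root hairs, one of 0.67 ± 0.22 (adjusted p = 0.190). Adjusted over each list alone, NDB2, WRKY6, EXPA18, HCT and the glutathione transferase gene GSTU25 (0.70 ± 0.26) rose and SIM fell. With the block ATHSP22.0 passed in this way too, at means of only 0.64 in boric acid and 0.31 in control. Over all genes it did not pass with the block in limma (adjusted p = 0.204). HCT, GSTU25, SIM and ATHSP22.0 are the only measured members of their lists, so for them adjusting over the list leaves the unadjusted p. GSTU25 does not stand for its family. Of 11 measured genes with GSTU symbols, grouped later, 2 fell and 0 rose over all genes. With the block 3 fell and 2 rose. Of the 2 measured green tissue markers, LHCB4.1 had the larger change, -0.22 ± 0.27. In a list of photosystem and light harvesting genes written later, none of 5 measured members passed in limma and 2 had an unadjusted p under 0.05, LHCB4.2 with a change of -0.99 ± 0.33 (adjusted p = 0.187) and PSBY with one of -0.63 ± 0.24 (adjusted p = 0.256). The clock gene GI had a change of -0.16 ± 0.82, and its values on the arrays numbered 1 stood apart at 2.42 and 3.06 against 0.36 to 0.75 on the others. Largest changes in the other lists were -0.35 ± 0.22 for ARR15 (cytokinin), -0.37 ± 0.20 for RTE1 (ethylene), 0.26 ± 0.14 for ATLIG4 (DNA damage), 0.33 ± 0.19 for ATHSP22.0 (heat shock), -0.10 ± 0.10 for DFR (flavonoids), 0.10 ± 0.13 for BGLU28 (sulfur starvation) and 0.03 ± 0.33 for BZIP60 (unfolded protein response). No gene with a probe set of its own was named for the lists of aquaporins, hypoxia, nitrate and ammonium, Casparian strip and suberin, cellulose synthases, cytosolic ribosomal proteins, abscisic acid synthesis, breakdown and receptors, and phloem and xylem.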

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

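The groups of 3 arrays are too small for a test of an outlying array. The tests of other groupings of the arrays and of RNA quality in this part were chosen after their results had been seen. The late embryogenesis abundant, seed, green tissue and clock tests were written after the patterns had been seen and before their own results.

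The 362 genes past the threshold were compared with other groupings. The 6 arrays can be split into groups of 3 in 10 ways, so the share of splits with as many genes is never under 0.1. The real split gave 362 genes and the highest of the other 9 gave 0 (1 of 10 as large as the real one). At an unadjusted limma p under 0.05 it gave 1993 genes, against 1353 for boric acid 1, boric acid 2 and control 1 against the rest. At that unadjusted p, the 3 other splits that also part all 3 same-numbered pairs gave 120, 139 and 327 genes, and the 6 that keep 2 such pairs together gave 206 to 1353.

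Late embryogenesis abundant genes stood out among the largest rises, with AT3G02480 and LEA4-5 at changes of 5.997 and 4.97. A rise of the family as a whole was tested on the 28 measured members that had not been seen before: 1 rose (2 with the replicate block), their mean change was 0.07 ± 0.08 (SE), and limma's camera, run as a single test, gave a p of 0.755. These values met the bound set beforehand, but that bound was wrong, since the 28 leave out 5 of the 6 members that rose, so a rise of the family stays open. In addition, 21 of the 28 had a mean level under 1, with a median level of 0.24, near background, where a change may go undetected. RNA of seeds, in which the family is abundant, was argued against by the 4 measured seed storage and oil body genes, whose median change was -0.0605 with an SD of 0.06, short of the rise of 1 that was to count for it, and of which none passed, even at an unadjusted limma p under 0.05. All lay under 1 in both groups, from where LEA4-5 rose. Most genes written for that list had no named probe set, so the argument covers these 4 alone. A response of single family members to boric acid is a possible biological explanation, and no test of it was made.

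The arrays numbered 1 stood apart on the second principal component, and 647 genes (4.84%) passed limma's threshold between them and the other 4 arrays, 316 higher and 331 lower, of which 5 also passed for boric acid. So small an overlap is favoured by the fit without the block, where the deviation of these arrays adds to the spread within each group. Green tissue in these samples stays open: 5 photosystem and light harvesting genes had a median deviation on the array numbered 1 of 0.549 ± 0.21 in boric acid and -0.49 ± 0.35 in control, with SEs that allow for their estimated correlation (a choice made after the values were seen), and neither bound set beforehand was met. A further candidate explanation that stays open is 3′ bias of the RNA, since actin and GAPDH, 2 of 3 control genes, had their highest 3′ to 5′ differences on both arrays and ubiquitin did not. Another time of day could not be decided from 6 clock and day-rhythm genes not seen before, of which 1 passed (one-sided Fisher exact p = 0.257). No biological explanation from the design was tested.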

How the results depend on the processing

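The fits without both arrays numbered 1, the test of lists with 1 or 2 members and the family tests were chosen after the data had been examined. Against 362 genes, 1047 passed with the replicate block, 675 with array weights, 205 with a 2-fold minimum and 56 at an adjusted p under 0.01. Without both arrays numbered 1, 809 passed, 300 of them among the 362. Without 1 array the count ranged from 36 to 573. The minimum and the lower threshold reduce the count by construction, and for the others the cause was not tested. Trend and robust moderation, both scalings, both filters on dim probe sets, the mean of probe sets and leaving out cross-hybridizing ones gave 332 to 377 genes, of which 275 to 358 were among the 362. The share higher was 56.8% and 57.7% under the scalings, against 59.7%. Of 9 gene lists, 2 passed, and 0 with an estimated correlation in limma's camera, where 2 had an unadjusted p under 0.05. The same 2 passed in every other setting, with the iron deficiency list added under the block. Among the genes the rule names, the list members (over all genes or over the list alone) and the 9 lists tested, the block changed no other call than those given with the results.

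All 29 named genes past the threshold kept their call under the block, both scalings, trend and robust moderation, the filter on the dimmest 25% and the mean of probe sets, and 1 lost it without both arrays numbered 1. None turned its sign in these settings or without 1 array. Signs turned for 5 genes not past the threshold. AT5G25430 had -0.0029 with median centring. Without 1 array, changes ranged from -0.0735 to 0.1191 for AT5G25430, -0.54 to 0.27 for PRL, -0.19 to 0.36 for BZIP60, -0.40 to 0.0357 for LHCB4.1 and -0.76 to 0.67 for GI, and GI had 0.0719 without both arrays numbered 1. The cause was not tested. Values near 0 hold mostly background, so folds against them, as for BCAT4, are of uncertain size.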

Other observations

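The families and gene lists of this part were chosen after the data had been examined, and the tests on glucosinolate genes not seen before and on neighbouring genes were written before their results.

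Families of genes whose symbols share a stem were tested with limma's camera, and 2 of 33 passed after Benjamini-Hochberg adjustment. All 11 measured ATG genes, of which most encode the ATG8 proteins that coat autophagy membranes, had a positive change, with a median of 0.38 (adjusted p = 0.000522, and adjusted p = 0.349 with an estimated correlation of -0.030). That estimate lies under the preset, so this loss does not come from members that vary together. ATG8H rose by 0.69 ± 0.10 (SE, adjusted p = 0.0256). APG8A (change 0.60 ± 0.13 without the block) and ATG8B (0.74 ± 0.19 without the block) rose with the replicate block (adjusted p = 0.0369 and 0.0297). Of 12 measured UBP genes, which encode ubiquitin-specific proteases, 11 had a positive change, with a median of 0.29 (adjusted p = 0.00366, and adjusted p = 0.403 with an estimated correlation of 0.025). UBP21 rose by 0.59 ± 0.10 (adjusted p = 0.0350). UBP22 (1.14 ± 0.27 without the block) and UBP15 (0.83 ± 0.21 without the block) rose with the block (adjusted p = 0.0497 and 0.0283). The counts of positive changes were the same under both scalings. With an estimated correlation none of the 33 families passed, while 3 had an unadjusted p under 0.05. Since ATG lost its call at an estimate under the preset, the loss for UBP need not come from correlation either. Without 1 array both passed each time, with adjusted p up to 0.0195 for ATG and 0.0396 for UBP. The next family, TBL, which includes acetylases of cell wall polymers, had 7 of 23 changes positive and did not pass (adjusted p = 0.0568).

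Genes of glucosinolate synthesis and transport were listed because BCAT4, GTR2, UGT74B1 and GSTU20 had been seen with large negative changes, so the direction of the full list is no independent evidence. Of its 7 measured members 3 fell: BCAT4, the transporter GTR2 (change -1.47 ± 0.20 SE, adjusted p = 0.0179) and the glucosyltransferase UGT74B1 (-1.22 ± 0.14, adjusted p = 0.0117). With the replicate block GSTU20 (-1.57 ± 0.28 SE of the block fit, adjusted p = 0.0289) and AT2G31790 (-1.35 ± 0.19, adjusted p = 0.0150) fell too. All 7 changes were negative, except that 1 was positive when quantile normalization was applied again. The full list gave a p of 1.28e-06 in limma's camera, and 0.0475 with an estimated correlation. The hypothesis that the group falls together was tested on the 3 members not seen before, GTR1, AOP3 and AT2G31790. Their median change was -0.23, short of the -0.5 that was to count for a shared fall. None passed over all genes and 1 had an unadjusted limma p under 0.05, and with 3 members, 1 of them near background, the test leaves the hypothesis open.

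The rises of late embryogenesis abundant genes were not limited to the largest. Of 35 measured members, 6 rose and none fell: besides AT3G02480, LEA4-5 and LTI30 these were AT2G23110 (change 2.16 ± 0.24 SE, adjusted p = 0.0112), LEA18 (1.33 ± 0.19, adjusted p = 0.0206) and AT2G23120 (1.05 ± 0.14, adjusted p = 0.0174). With the replicate block AT3G17520 (1.75 ± 0.35, adjusted p = 0.0532, and 0.0114 with the block) rose too, which makes 7. The median change of the 35 was 0.01, with 18 positive, and under median centring -0.01, with 17 positive. Of the 35, 22 had a mean level under 1, with a median level of 0.28 for the list, so this median mostly reflects genes near background. As a list they gave the direction up with a p of 0.00457 in limma's camera (0.00744 with the block), and a p of 0.0832 with an estimated correlation. Since 7 members had been seen before the list was written, this is no independent evidence of its direction.

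AT2G23110 and AT2G23120 are neighbours in the genome, as are AT4G29690 and AT4G29700 (-2.31 and -1.75) and AT1G14210 and AT1G14220 (-1.18 and -2.04). The hypothesis that neighbouring genes change together more often than by chance was tested on 5849 adjacent measured pairs. In 3 pairs both genes were past the threshold in the same direction, and in 3 pairs in opposite directions. Shuffling the calls 10000 times gave a mean of 2.77 same-direction pairs and at most 11 (one-sided permutation p = 0.521). The pair of AT4G29690 and AT4G29700 had been noticed before the test, and so few pairs leave a weak tendency open.

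Between the arrays numbered 1 and the other 4, AT5G15950 differed by 4.62 ± 0.55 (SE, limma, adjusted p = 0.00784), AT3G44450 by 3.09 ± 0.23 (adjusted p = 0.00202) and the clock gene GI by 2.15 ± 0.19 (adjusted p = 0.00382). AT5G61590 differed by -4.53 ± 0.38 (adjusted p = 0.00295) and AT5G60680 by -4.36 ± 0.12 (adjusted p = 6.59e-05). None of these 5 was past the threshold for boric acid in the fit without the block. There the deviation of the arrays numbered 1 adds to the spread within each group. Genes picked for that deviation could hardly pass, so this does not show that boric acid left them unchanged.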
